A study of Mus musculus with 6 samples.

How the data were processed

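RNA was sequenced from mouse bone marrow-derived macrophages (BMDMs) in 6 libraries, 2 in each of 3 groups (control, LPS, and LPS in cells labelled as overexpressing Glul from a lentiviral vector, called Glul_LPS). The libraries were prepared with a NEBNext Ultra kit and sequenced on an Illumina HiSeq, per the labels' protocols. The authors deposited 1 table with a FPKM value (fragments scaled by transcript length and by library size) for each of 24752 genes. The submitters' processing notes name CASAVA, HISAT2 2.1.0, HTSeq 0.6.0, the genome build GRCm38 and, among the tools the authors listed, DESeq2. The order of these steps, the gene annotation and the strand setting are not given in the sources used here. 6 further columns of per-sample values match no listed sample, so their groups are unknown, and they were not used here.

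The unit was checked on the values. In each library, FPKM times exon length gave whole fragments, within 0.01 of a fragment, for 99.96% to 99.97% of genes with 1 exon, for a library total that was itself recovered from the table. Those totals were 18691669 and 17333625 fragments for control B and C, 16103044 and 17100908 for LPS B and C, and 17019324 and 15649764 for Glul_LPS B and C. A gene of 1 kilobase with 1 fragment had between 0.0535 and 0.0639 FPKM at these depths. Whole fragments were recovered in all 6 libraries for 22655 genes. Gene positions and names were those of the deposited table, and 24703 of its gene IDs were found in GENCODE M21, which supplied exon lengths.

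Values were analysed as log2(FPKM + 1), with no further scaling between libraries. A log2 change on this scale understates the fold of genes near or below 1 FPKM. Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested, which left 10962. All 3 groups entered one limma fit (limma 3.58.1 under R 4.3.3, moderated test with a mean-variance trend, two-sided, 6.27 degrees of freedom in total), with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The 3 comparisons were LPS with control, Glul_LPS with LPS, and Glul_LPS with control. "Rose" and "fell" are used for genes and lists past that threshold. No Glul group without LPS was among the samples, so an interaction of Glul and LPS could not be tested. Nothing in the labels says whether the 2 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

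Before the data were examined, 32 gene lists holding 598 genes were fixed, and 617 of their 627 entries were found in the table by symbol. Lists with at least 5 tested members (28 of 32) were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Camera was run again with an estimated correlation, and fry was run as a test of each list on its own (statmod 1.5.0). With an estimated correlation, camera rests on the few residual degrees of freedom of the fit, which by itself raises the p. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes named in the text followed a rule fixed at the same time. It allowed Glul, up to 10 genes per direction and comparison with the largest change among those past the threshold with a mean of at least 5 FPKM in the higher group and replicates that did not overlap, up to 4 members of each list, 10 cytokine, chemokine and metabolic genes for Glul_LPS with LPS whatever their result, and the most abundant markers of other cell types. Predicted genes, pseudogenes and ribosomal protein genes were left out of the ranked part.

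The calls were tested on simulated fragments drawn from real means and library totals. The groups compared had the same means except for the changed genes, and genes were drawn independently. The rates below therefore do not describe a comparison in which most genes change, such as the real LPS with control. For LPS with control (9780 genes), 22%, 64%, 94% and 90% of 50 genes each were recovered at folds of 1.3, 1.5, 2 and 4, and 13.6% of 169 calls were false. For Glul_LPS with LPS (9606 genes), the shares were 20%, 38%, 76% and 86%, and 10.1% of 138 calls were false, above the nominal rate. A list of 20 members changed by 1.5-fold was called in both simulated comparisons, and 0 of the other lists were. As the simulated genes were independent, this does not measure false list calls among correlated genes.

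Alternatives fixed together with the lists were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, rescaling to TPM, quantile normalization, centring on the median, a fit of only the 2 groups compared, the replicate letter as a block, no mean-variance trend, a robust spread, a minimum change of 1 on the log2 scale, and leaving out each library in turn. Limma voom on the recovered fragments, and median centring of the list tests, were chosen after seeing the data. The covariance of 2 comparisons that share the LPS libraries was set beside 100 simulations of unchanged groups, and the division of the LPS libraries between them was chosen after seeing the data. The mean covariance of the divisions was tested with a t test against the covariances of replicate differences with the LPS change, so that correlation between genes was kept. Stretches of 50 bases of 112 genes considered for the text were searched for in all other transcripts of GENCODE M21 (Python 3.11.15), and gene ontology terms were tested with a one-sided Fisher's exact test (SciPy 1.17.1).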

Results

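RNA levels were measured in mouse bone marrow-derived macrophages (BMDMs), cells grown from bone marrow precursors for 7 days. The 6 libraries formed 3 groups of 2, with replicates named B and C after the labels. The groups were control, LPS and Glul_LPS. LPS (lipopolysaccharide, a bacterial cell wall component sensed by Toll-like receptor 4) was given at 100 ng/ml for 3 h. Per the labels' protocols, lentiviral vectors, either control or overexpressing Glul, were applied for 36 h before LPS, and the labels do not say which vector, if any, the control and LPS libraries carried. Depth was 18691669 and 17333625 fragments in control B and C, 16103044 and 17100908 in LPS B and C, and 17019324 and 15649764 in Glul_LPS B and C. Replicates correlated across genes at 0.9935 (control), 0.9943 (LPS) and 0.9938 (Glul_LPS) on the log2 scale, where genes are not independent replicates. Their differences exceeded counting error, with a chi-square per gene of 3.38, 5.08 and 4.78.

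Glul encodes glutamine synthetase, which makes glutamine from glutamate and ammonia, and it was the gene named as overexpressed. Glul (ENSMUSG00000026473, protein-coding, chromosome 1, 153899944 to 153909723 on the plus strand of GRCm38) stood at 140 FPKM in both control libraries, 30.6 and 33.4 FPKM in LPS B and C, and 37.2 and 37.7 FPKM in the libraries labelled as overexpressing Glul, Glul_LPS B and C. These values rested on 1635 to 8711 fragments per library. Glul fell with LPS by 2.1 on the log2 scale (SE 0.06, adjusted p = 6.32e-07), from 140 ± 0.0479 to 32 ± 2.02 FPKM (SD, n = 2 each), and by 1.60 relative to the median gene. Between Glul_LPS (37.5 ± 0.397 FPKM) and LPS the ratio was 1.17 (95% interval 1.06 to 1.28) and the change of 0.22 did not pass the threshold (adjusted p = 0.122). In limma voom on recovered fragments, chosen after seeing the data, it was 0.23 and passed (adjusted p = 0.0451). Glul was lower in Glul_LPS than in control (log2 change −1.88, adjusted p = 1.05e-06). Reads of a vector-borne copy count toward Glul only where the copy holds the sequence of the annotated gene, and 12.6% of its 50-base stretches also lie in other transcripts, among them the pseudogene Glns-ps1.

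LPS with control asked how LPS changed these macrophages. Among the lists tested, inflammatory cytokines, interferon-stimulated genes and chemokines had the largest median rises, 3.92, 3.88 and 3.44 on the log2 scale. Cxcl10, a chemokine that attracts T cells, went from 15.3 ± 0.241 to 2910 ± 79.3 FPKM (SD, n = 2 each), a log2 change of 7.48 (SE 0.05, adjusted p = 1.23e-08). Rsad2, an antiviral enzyme, went from 14.6 ± 0.907 to 2740 ± 167 FPKM (log2 change 7.46), and Nos2, which makes nitric oxide, from 0.205 ± 0.0869 to 130 ± 19.9 FPKM (log2 change 6.76). In the other direction Cxcr4, the receptor for Cxcl12, fell from 131 ± 11.4 to 1.24 ± 0.489 FPKM (log2 change −5.89, SE 0.15, adjusted p = 5.62e-07). The median gene was 0.50 lower on the log2 scale in LPS, a shift that was −0.56 in TPM, −0.13 after quantile normalization and 0.02 after centring. Counts below are therefore given as deposited and, as "relative to the median", after each library was centred on its median gene.

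All 38 tested interferon-stimulated genes rose, as deposited and relative to the median (adjusted p = 1.43e-39, but adjusted p = 0.155 with an estimated correlation), among them Rsad2, Ifit1 (log2 change 7.10), an antiviral RNA-binding protein, and Cmpk2 (7.08). Of 19 inflammatory cytokines, 18 rose and 1 fell on both scales (adjusted p = 4.07e-17, but adjusted p = 0.102 with an estimated correlation), among them Il1a (7.02), Il27 (6.82) and Il6 (6.46). Of 18 chemokines, 17 rose and 1 fell on both scales (adjusted p = 3.78e-16, but adjusted p = 0.102 with an estimated correlation), among them Ccl4 (6.50) and Cxcl9 (6.19). The classical activation markers, a list of genes of inflammatory macrophages, had 19 of 20 members up and 1 down, and 19 up and 0 down relative to the median (adjusted p = 4.53e-17, but adjusted p = 0.102 with an estimated correlation). They included Mmp13 (6.66), a collagenase, the costimulatory receptor Cd40 (5.70) and Ptgs2 (5.44), the inducible cyclooxygenase. Adjusted over the list alone, the counts of these 4 lists were the same as deposited.

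The NF-kB pathway and feedback list had 23 of 26 members up and 1 down, 24 up and 1 down adjusted over the list alone, and 25 up and 0 down relative to the median (adjusted p = 3.85e-20, but adjusted p = 0.102 with an estimated correlation). Dusp2 (log2 change 4.01), a phosphatase of MAP kinases, and Tnfaip3 (3.38), an inhibitor of NF-kB, were among those that rose. Of 18 MHC class I genes, which present peptides to cytotoxic T cells, 15 rose and 1 fell, and 17 rose and 0 fell relative to the median (adjusted p = 5.71e-11, but adjusted p = 0.102 with an estimated correlation), including the peptide transporter Tap1 (2.51). Of 18 inflammasome and cell death genes, 11 rose and 6 fell, and 15 rose and 2 fell relative to the median (adjusted p = 2.51e-05, but adjusted p = 0.102 with an estimated correlation), including Il1b (3.57) and the sensor Nlrp3 (1.65). The arginine and polyamine list was called higher with 4 of 15 members up and 6 down, 9 up and 3 down relative to the median (adjusted p = 0.0344, but adjusted p = 0.231 with an estimated correlation). Its largest rises were Nos2 and the arginine transporter Slc7a2 (4.58). The TLR4 signalling components were also called higher (adjusted p = 0.046, but adjusted p = 0.231 with an estimated correlation), with 9 of 23 up and 10 down, 14 up and 7 down relative to the median, a median log2 change of −0.19 and a mean of 0.00. The adaptor Myd88 (1.82) and the kinase Map3k8 (1.63) rose, and the kinase Irak4 (−1.35) fell. Adjusted over the list alone, these 4 lists other than NF-kB kept those counts, and the arginine list lost its call without control C (adjusted p = 0.0517) or LPS C (adjusted p = 0.0573), and the TLR4 list without control C (adjusted p = 0.0635). Scaling and filter also ended both calls, with adjusted p = 0.131 (arginine) and 0.18 (TLR4) after median centring, 0.193 and 0.0756 after quantile normalization, and 0.0769 and 0.105 with no filter, and the replicate block ended that of TLR4 (adjusted p = 0.0551).

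Of 26 tested glutamine and glutamate genes, 4 rose and 18 fell, also adjusted over the list alone, and 7 rose and 9 fell relative to the median (list adjusted p = 0.513). Beside Glul, the glutamine transporter Slc38a2 (log2 change −2.09) and the aspartate aminotransferase Got1 (−1.65) fell, and the cystine-glutamate exchanger Slc7a11 (1.72) rose. Of 24 genes of the tricarboxylic acid cycle, 0 rose and 22 fell, 23 adjusted over the list alone, while relative to the median 5 rose and 7 fell (list adjusted p = 0.0567). Idh1 (−1.57), the cytosolic isocitrate dehydrogenase, and Aco1 (−1.04), the cytosolic aconitase, were the largest falls named. Of 22 glycolysis genes, 6 rose and 13 fell, also adjusted over the list alone, and 10 rose and 9 fell relative to the median (list adjusted p = 0.584). The hexokinase Hk2 rose from 12.7 ± 1.24 to 66.2 ± 1.57 FPKM (log2 change 2.30), and Pfkfb3, which makes an activator of phosphofructokinase, rose from 9.02 ± 0.277 to 42.1 ± 2.45 FPKM. Of 20 NRF2 targets, genes of the antioxidant response, 5 rose and 14 fell, also adjusted over the list alone, and 6 rose and 10 fell relative to the median (list adjusted p = 0.779). Gclc (−2.25) and Gclm (−1.72), which make the rate-limiting enzyme of glutathione synthesis, fell.

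Of 21 macrophage identity genes, 2 rose and 15 fell, also adjusted over the list alone, and 10 rose and 4 fell relative to the median (list adjusted p = 0.779). The M-CSF receptor Csf1r fell from 678 ± 3.32 to 302 ± 14.6 FPKM (log2 change −1.16). Further falls past the threshold were those of the transcription factors Cebpa (−4.51) and Id3 (−3.90), and of the stress-response gene Sesn1 (−4.50). Of 15 immediate early genes, 6 rose and 5 fell, also adjusted over the list alone, and 8 rose and 5 fell relative to the median (list adjusted p = 0.131), with Maff (2.24) up and Fos (−3.32) and Nr4a1 (−3.22) down. Of 12 mitochondrially encoded genes, 0 rose and 10 fell, also adjusted over the list alone, and 2 rose and 0 fell relative to the median, with a median log2 change of −0.42 (list adjusted p = 0.513). Of 18 cell cycle genes, 1 rose and 14 fell, also adjusted over the list alone, and 4 rose and 10 fell relative to the median (list adjusted p = 0.529). The proliferation marker Mki67 rose (1.75), while Mcm3 (−1.33), part of the replicative helicase, fell. Among markers of other cell types, the highest mean over all libraries was 108 FPKM for osteoclasts (Atp6v0d2, also on the lysosome list), 52.7 for neutrophils (Csf3r), 31.9 for dendritic cells (Itgax), 25.3 for megakaryocytes (Pf4), 17.5 for lymphocytes (Ighm), 4.31 for mast cells (Hdc) and 3.12 for stromal cells. Hdc, the histamine-making enzyme listed for mast cells, rose from 0.159 ± 0.0837 to 6.53 ± 0.331 FPKM, and Lck, a T cell kinase, from 0.142 ± 0.00583 to 3.55 ± 0.282 FPKM.

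In total 9338 of 10962 genes passed the threshold in LPS with control, 1879 higher and 7459 lower (20.1% higher), with 821 at least 1 log2 unit higher and 2164 at least 1 lower. After median centring 7318 passed, 3788 higher and 3530 lower (51.8% higher), with 1388 and 671 at least 1 log2 unit up and down. Of the 28 lists tested, 9 were called, all higher, and none with an estimated correlation, where the smallest adjusted p was 0.102. The estimated correlation of MHC class I was 0.009, close to the preset 0.01. The residual degrees of freedom of that test, and not correlation, thus ended its call. Estimates for the other called lists ran from −0.022 (arginine and polyamine) to 0.515 (interferon-stimulated genes). Where the estimate exceeded the preset, correlation may also have raised the p, and the p at the preset may be too small. Directions of genes that moved by less than the median shift depend on the scaling.

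**Figure D1:**
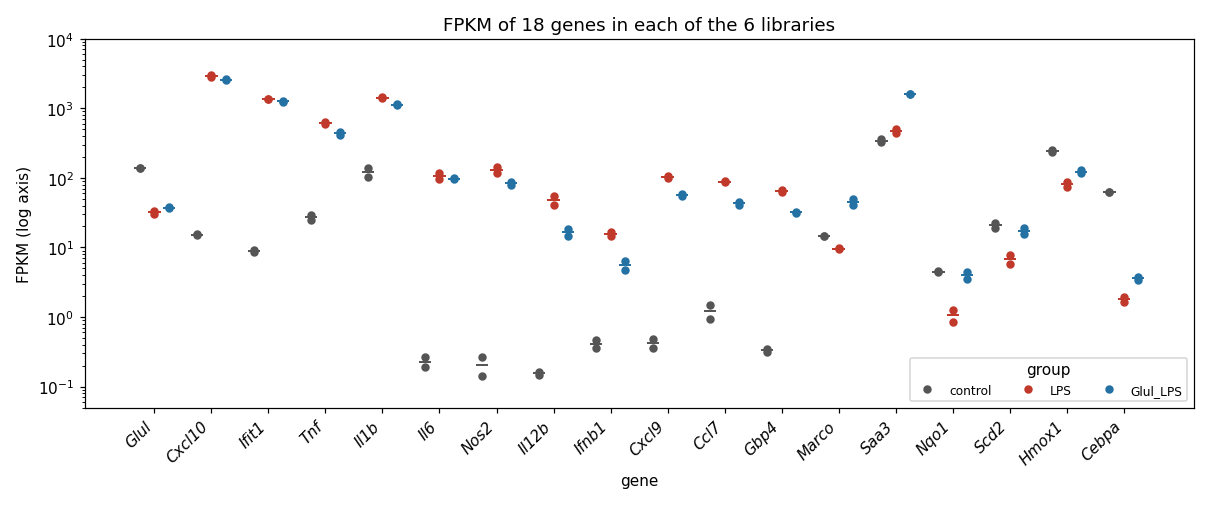
FPKM (log axis) of 18 genes in the 6 libraries, with points for libraries and bars for group means. Glul lies at 140 FPKM in control and between 30.6 and 37.7 FPKM in the 4 LPS-treated libraries, while Cxcl10 goes from 15.3 to 2910 and 2560 FPKM.

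Glul_LPS with LPS addressed the question of the series, how cells labelled as overexpressing Glul differ from other LPS-treated cells, while Glul itself did not pass the threshold between these groups. The scavenger receptor Marco, which binds bacteria, was higher in Glul_LPS, at 45.5 ± 6.97 against 9.6 ± 0.3 FPKM (SD, n = 2 each, log2 change 2.12, SE 0.10, adjusted p = 0.00241). The acute-phase gene Saa3 rose from 474 ± 46.5 to 1610 ± 10.2 FPKM (log2 change 1.76, SE 0.08, adjusted p = 0.00241). Il12b, the p40 subunit of interleukins that drive T cell responses, fell from 47.3 ± 10.1 to 16.6 ± 2.77 FPKM (log2 change −1.45, SE 0.16, adjusted p = 0.0242), and Ifnb1, interferon beta, from 15.5 ± 1.33 to 5.6 ± 1.17 FPKM (log2 change −1.33, SE 0.13, adjusted p = 0.0207). The median gene differed by 0.02 between the groups. Compared with the effect of LPS itself these changes were small, and 17 genes passed the threshold with at least 1 log2 unit.

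Among the inflammatory lists, chemokines, MHC class I, interferon-stimulated genes, cytokines and the NF-kB list were called lower in Glul_LPS, but none with an estimated correlation (adjusted p = 0.256, 0.232, 0.49, 0.49 and 0.49). The classical activation and inflammasome lists were not called, and of 18 inflammasome and cell death genes 0 passed, also adjusted over the list alone (list adjusted p = 0.153). Of 18 chemokines, 17 lay below 0, and 5 fell and 0 rose (11 fell adjusted over the list alone), with a median log2 change of −0.33 (adjusted p = 1.29e-11, but adjusted p = 0.256 with an estimated correlation). Ccl7 (−1.02) and Ccl6 (−0.75) fell, as did Cxcl9, from 102 ± 4.9 to 56.6 ± 2.08 FPKM (−0.84), and Cxcl11, of which 40.4% of the 50-base stretches also lie in other transcripts. All 18 MHC class I genes lay below 0, and 3 fell (7 adjusted over the list alone), with a median of −0.17 (adjusted p = 4.55e-09, but adjusted p = 0.232 with an estimated correlation). They were H2-Q6 (−1.21), H2-Q7 (−0.87) and H2-K1 (−0.39), and 35.0% and 26.5% of the stretches of H2-Q6 and H2-Q7 are shared, largely between relatives. Of 38 interferon-stimulated genes, 36 lay below 0 and 2 fell, Ifnb1 and Oasl1 (11 fell adjusted over the list alone), with a median of −0.15 (adjusted p = 2.55e-11, but adjusted p = 0.49 with an estimated correlation). The guanylate-binding protein Gbp4, also induced by interferons, fell from 64.6 ± 2.13 to 32 ± 0.9 FPKM (−0.99, adjusted p = 0.00488).

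Of 19 inflammatory cytokines, 3 fell and 0 rose (7 fell and 3 rose adjusted over the list alone), with a median of −0.19 (adjusted p = 8.39e-05, but adjusted p = 0.49 with an estimated correlation). They were Il12b, Il1a, which fell from 686 ± 23.9 to 361 ± 19 FPKM, and Il27 (−0.55). Exons of Il1a overlap those of Gm14023 over 11.2% of their bases, and those of Il27 overlap Apobr over 10.1%. The NF-kB list was called lower (adjusted p = 0.00142, but adjusted p = 0.49 with an estimated correlation), with a median of −0.08 and 2 members that fell (4 adjusted over the list alone), Tnfaip3 (−0.46) and the adhesion molecule Icam1 (−0.39). Tnf was 435 ± 23.8 against 609 ± 24.2 FPKM, a log2 change of −0.48 that did not pass (adjusted p = 0.0773). The same held for Nos2 (−0.63, adjusted p = 0.0671), Ccl2 (−0.78, adjusted p = 0.118), Il1b (−0.33, adjusted p = 0.266), Cxcl10 (−0.18, adjusted p = 0.133), Il6 (−0.13, adjusted p = 0.551), Ifit1 (−0.10, adjusted p = 0.373) and the anti-inflammatory cytokine Il10 (0.28, adjusted p = 0.135). The values of Il6 and Ifit1 changed sign in an alternative, Il6 to 0.01 without LPS B and Ifit1 to 0.02 after quantile normalization. Immediate early genes were called lower as a list (median −0.14, adjusted p = 0.0115, but adjusted p = 0.49 with an estimated correlation), with 2 down, Maff and Atf3 (−0.35), and 1 up, Fos (0.69), and with 4 down and 2 up adjusted over the list alone. The alternative activation markers had a median of −0.20 and 0 members past the threshold (5 fell and 1 rose adjusted over the list alone, list adjusted p = 0.0398, but adjusted p = 0.49 with an estimated correlation). The immediate early list lost its call without LPS C (adjusted p = 0.0977) or Glul_LPS B (adjusted p = 0.0825) and in TPM (adjusted p = 0.0506). The alternative activation list lost it without the same libraries (adjusted p = 0.18 and 0.0663), and with no filter, in TPM, after quantile normalization, after centring and with the replicate block (adjusted p = 0.19, 0.137, 0.0568, 0.067 and 0.0725).

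NRF2 targets were higher in Glul_LPS. Of 20 members 7 rose and 0 fell (14 rose adjusted over the list alone), with a median of 0.32 (adjusted p = 4.23e-11, but adjusted p = 0.49 with an estimated correlation). Nqo1, a quinone reductase, rose from 1.06 ± 0.311 to 3.96 ± 0.625 FPKM (log2 change 1.27), the heme oxygenase Hmox1 from 80.9 ± 8.72 to 123 ± 8.48 FPKM (0.61), and the ferritin heavy chain Fth1 from 15500 ± 702 to 21400 ± 209 FPKM (0.46). Of 18 cholesterol genes, 15 lay above 0 and 2 rose (6 adjusted over the list alone), the desaturase Scd2 (1.24) and the sterol synthesis enzyme Hmgcs1 (0.62), with a median of 0.17 (adjusted p = 0.00212, but adjusted p = 0.516 with an estimated correlation). In Hmgcs1, 11.6% of the stretches lie in other transcripts, and without Glul_LPS C the list lost its call (adjusted p = 0.0625). All 12 mitochondrially encoded genes lay above 0, with a median of 0.14 and 0 past the threshold on either count, over all genes or adjusted over the list alone (list adjusted p = 0.00355, but adjusted p = 0.516 with an estimated correlation), and without Glul_LPS B the adjusted p was 0.0515. Of 21 macrophage identity genes, 18 lay above 0 with a median of 0.08 and 0 past the threshold, while 7 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00452, but adjusted p = 0.49 with an estimated correlation). Adgre1, which encodes the macrophage marker F4/80, stood at 621 ± 65.7 against 451 ± 1.94 FPKM (0.46, adjusted p = 0.0626).

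Genes of glutamine metabolism, the pathway of Glul, showed no call. Among 26 glutamine and glutamate genes 0 passed the threshold (2 rose and 0 fell adjusted over the list alone), the median was 0.06 and the list adjusted p = 0.674. The tricarboxylic acid cycle (median 0.00, list adjusted p = 0.872) and glycolysis (median 0.04, list adjusted p = 0.94) had 0 members past the threshold, and adjusted over the list alone 0 of the former and 3 up and 3 down of the latter. The classical activation markers split, with 3 up, Marco, Saa3 and the siderophore-binding Lcn2, and 1 down, the costimulatory Cd80 (−0.67), a median of −0.14, a mean of 0.17 and no call (list adjusted p = 0.597, 6 up and 8 down adjusted over the list alone). Of 18 ATF4 targets, genes of the amino acid response, 2 fell, Atf3 and Ddit3 (−0.37), and 0 rose (3 fell and 2 rose adjusted over the list alone, list adjusted p = 0.795). Other genes with large rises were the dicarboxylate transporter Slc13a3 (1.48), the inhibitory lectin Siglece (1.38), Lox (0.89), Cd5l (0.87), Atf5 (0.85) and Ednrb (0.84). Itgax, the integrin CD11c that is listed for dendritic cells and also made by macrophages, fell from 36.1 ± 2.01 to 19.4 ± 3.46 FPKM. Of 5 neutrophil markers tested 0 passed (2 rose and 2 fell adjusted over the list alone, list adjusted p = 0.679). S100a9 (1.16 against 3.45 FPKM) and Ngp (0.172 against 1.09 FPKM, near the filter) were lower in both Glul_LPS libraries than in all 4 others. Csf3r (60.3 against 53.1 FPKM), Mmp8 (46.1 against 39 FPKM) and S100a8 (6.68 against 6.47 FPKM) had higher means than in LPS. S100a8 and S100a9 were named outside the naming rule, so that all 5 tested members are given. Ighg2b, an immunoglobulin gene, fell from 7.18 ± 0.894 to 3.04 ± 0.111 FPKM.

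In Glul_LPS with LPS 121 genes passed the threshold, 60 higher and 61 lower (133 after median centring, 53 higher and 80 lower), and 1915 had an unadjusted p below 0.05. The count was 57 without control B or without control C, 1 without LPS B, 4 without LPS C, 38 without Glul_LPS B and 5 without Glul_LPS C, and 9 with no filter, 264 at a mean of at least 5 FPKM, 55 in TPM, 59 with only the 2 groups, 42 with no mean-variance trend and 548 by voom, which was chosen after seeing the data. The 61 lower genes became 0 without LPS B, 0 without LPS C, 2 without Glul_LPS C, 19 without Glul_LPS B and 37 without either control library. In each of these fits every one of the 121 genes that was tested kept its direction. Leaving out a control library, fitting only the 2 groups, or changing the filter or the trend could not alter it. The remaining fits reused data that had selected these genes, so the kept direction is weak support. Of 28 lists 11 were called, 4 higher and 7 lower, 0 with an estimated correlation (smallest adjusted p = 0.232), and 2 by fry, the chemokines and MHC class I (adjusted p = 0.0385 each).

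**Figure D2:**
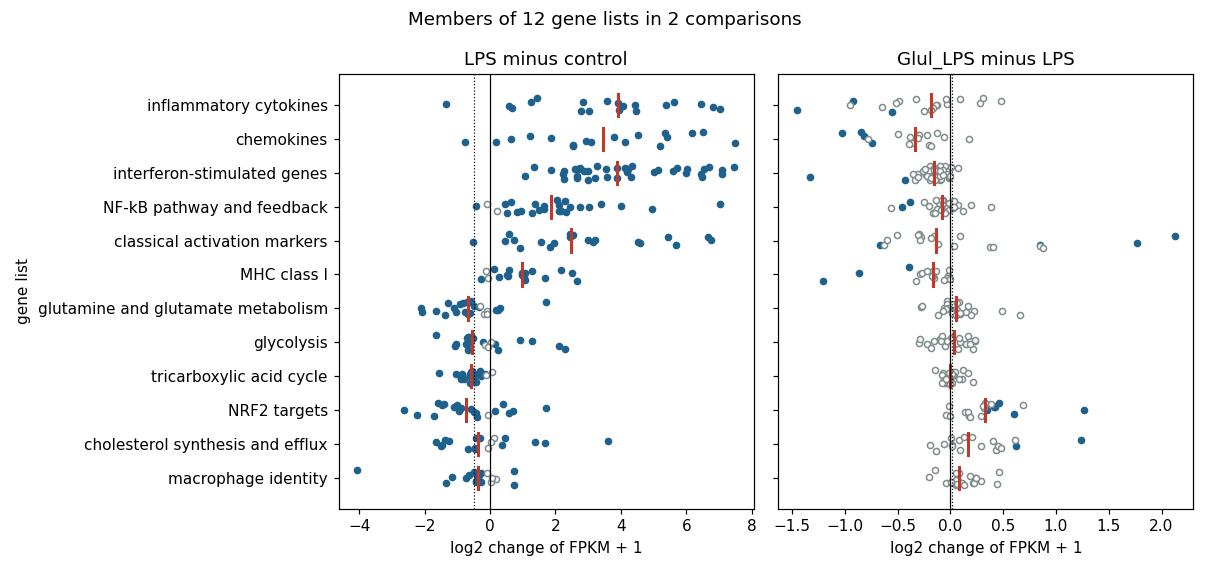
Log2 change of the tested members of 12 gene lists in LPS with control and in Glul_LPS with LPS, with filled points past the threshold, open points not past it, a red bar at the list median, a dotted line at the median of all tested genes and a solid line at 0. The chemokines lie at a median of 3.44 after LPS and −0.33 in Glul_LPS, and the NRF2 targets at −0.73 and 0.32, where the first is −0.23 relative to the median gene.

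The 2 comparisons were set side by side to ask which LPS-changed genes also differed in Glul_LPS. Of the 121 genes, 106 were also called in LPS with control, 89 in the opposite direction and 17 in the same. The genes raised by LPS and lower in Glul_LPS, such as Cxcl9, Il1a and Il12b, numbered 47, where independent lists would share 10.5. Those lowered by LPS and higher in Glul_LPS, such as Fos and Scd2, numbered 42, where 40.8 would be shared. Those lowered in both numbered 7, where 41.5 would be shared, and those raised in both 10, where 10.3 would be. These counts and expectations are as deposited, where LPS lowered 7459 genes, against 3530 after centring, so they depend on the scaling. Among the 153 genes that LPS raised by at least 3 log2 units, 141 lay below 0 in Glul_LPS with LPS, with a median of −0.22 (SD over genes 0.32), and 21 were called lower and 0 higher. Because the LPS libraries enter both comparisons with opposite signs, chance alone favours opposite directions. The covariance of the log2 changes across genes was −0.0701, where simulated unchanged groups of independent genes gave a mean of −0.0068. The correlation was −0.334 where they gave −0.501, and 63.5% of genes had opposite signs where they gave 66.6%. By these measures opposition was no stronger than in unchanged groups. The simulated groups held no LPS change, so their correlation and share of signs are not like for like with the real values. The LPS libraries were then divided between the comparisons, a test chosen after seeing the data. With LPS B set against control and LPS C against Glul_LPS the correlation was −0.193, and 57.6% of genes had opposite signs where independent signs would give 51.9%. With the libraries exchanged it was −0.310, with 64.4% where 53.3% would be given. Of the 160 and 138 genes at least 3 log2 units higher in that LPS library than in control, 82.5% and 93.5% lay below 0 in Glul_LPS against the other, where 46.3% and 43.8% of all genes did. Single libraries also differed along the LPS response. The mean covariance of these divisions was −0.0596, and the covariance of the replicate difference with the LPS change was 0.0304 for LPS B and C and −0.0066 for Glul_LPS B and C. Without single libraries the 106 genes became 52 (control B), 51 (control C), 1 (LPS B), 4 (LPS C), 34 (Glul_LPS B) and 5 (Glul_LPS C), and with no filter 6.

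Glul_LPS with control compared the libraries labelled as overexpressing Glul, under LPS, with control, and it isolates neither factor. Cxcl10 rose from 15.3 ± 0.241 to 2560 ± 78.3 FPKM (log2 change 7.30, SE 0.05, adjusted p = 1.56e-08), Rsad2 from 14.6 ± 0.907 to 2390 ± 21.9 FPKM, and the antiviral GTPase Mx1 from 11.2 ± 1.57 to 1000 ± 23.4 FPKM. Il6 (6.33) and Il27 (6.27) also rose. Cxcr4 fell from 131 ± 11.4 to 0.642 ± 0.0577 FPKM (log2 change −6.32), and Cd300lb (−4.61), Sesn1 (−4.39) and Id3 (−3.65) fell. All 38 interferon-stimulated genes rose, also adjusted over the list alone and relative to the median (adjusted p = 4.92e-40, but adjusted p = 0.153 with an estimated correlation). Of 19 inflammatory cytokines 18 rose and 1 fell on each of these counts (adjusted p = 2.6e-17, but adjusted p = 0.0923 with an estimated correlation). Of 24 tricarboxylic acid cycle genes 0 rose and 23 fell, also adjusted over the list alone, and 4 rose and 7 fell relative to the median (adjusted p = 0.0401, but adjusted p = 0.582 with an estimated correlation, and adjusted p = 0.356 after centring). Of 18 cholesterol genes 8 rose and 6 fell, also adjusted over the list alone, and 11 rose and 5 fell relative to the median (adjusted p = 0.017, but adjusted p = 0.747 with an estimated correlation, and adjusted p = 0.0547 with no filter, 0.0968 after quantile normalization and 0.195 after centring). In total 9241 genes passed, 1850 higher and 7391 lower (20% higher), with a median of −0.48, and after centring 7222 passed, 3751 higher and 3471 lower (51.9% higher). Of 28 lists 12 were called, 11 higher and 1 lower, 0 with an estimated correlation and 7 after median centring.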

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

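Voom on recovered fragments and the median centring of lists were chosen after the results were seen, and all other alternatives were fixed before. In LPS with control and in Glul_LPS with control, all named genes kept their direction and side of the threshold under all alternatives run (1276 and 197 values). The named genes were picked largely for large changes and do not stand for all calls. Of the 9338 calls in LPS with control, 7157 kept their direction after median centring and 7991 after quantile normalization. Of the 9241 in Glul_LPS with control, 7180 and 7989 did. In Glul_LPS with LPS, 625 values were unchanged in this sense, 281 kept the direction and no longer passed, 16 kept it and newly passed, and 2 changed sign. Of list results, 19 in LPS with control, 32 in Glul_LPS with LPS and 33 in Glul_LPS with control no longer passed under an alternative, and 107, 122 and 134 did.

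A mean of at least 5 FPKM, which left 5791 genes to test, gave 5055 genes in LPS with control and 4977 in Glul_LPS with control, and 264 in Glul_LPS with LPS, where the cause of the rise was not tested. A minimum of 1 on the log2 scale gave 2985, 17 and 2701, by construction. Glul_LPS with LPS had 9 genes with no filter (22955 tested) and 55 in TPM (13212 tested). It had 59 with only the 2 groups, 42 with no mean-variance trend and 548 by voom, where the cause was not tested. Leaving out single libraries gave 1 to 57, in fits that assume a lone library varies like the other groups. The count of LPS-changed genes also called there went from 106 to 6 with no filter, to between 1 and 52 without single libraries, and to 492 by voom. The log2 change of Glul between Glul_LPS and LPS was 0.229 by voom and passed (adjusted p = 0.0451), where the cause was not tested.

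With an estimated correlation, where the test rests on few residual degrees of freedom, 0 lists were called in LPS with control, 0 in Glul_LPS with LPS and 0 in Glul_LPS with control. With fry, which tests a list without comparing it with other genes, they were 24, 2 and 24. Median centring left 7 lists in Glul_LPS with control. The ATF4 list in Glul_LPS with control, called higher by camera, was called lower by fry (adjusted p = 0.0353). In Glul_LPS with LPS, 2 genes that did not pass changed sign. Ifit1 was 0.025 after quantile normalization, and Il6 ran from −0.272 without LPS replicate C to 0.011 without LPS replicate B. The causes were not tested.

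With the replicate letter as a block, 87 genes passed in Glul_LPS with LPS, 73 of them among the 121. Correlations of residuals between libraries of the same letter were −0.021, 0 and −0.047, so the values do not show the letters to be pairs. The quasi-likelihood test of edgeR was foreseen for a table with raw counts and was not run, as the values analysed here were FPKM. At this depth, 20% and 38% of simulated changes of 1.3-fold and 1.5-fold were recovered in Glul_LPS with LPS, so smaller differences may have been missed, with 1 to 57 genes called when single libraries were left out.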

Other observations

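The gene ontology tests and the genes outside the naming rule in the first paragraphs were chosen after the results were seen, as were all tests of explanations other than those of depth, of background reads alone and of unresponsive cells. Among the 61 genes lower in Glul_LPS than in LPS, 25 of 1307 gene ontology terms were over-represented (one-sided Fisher's exact test against 9138 tested genes with a term, 53 called genes with a term). These 61 calls became 0 without LPS B, 0 without LPS C and 2 without Glul_LPS C, 19 without Glul_LPS B and 37 without either control library. Defense response to bacterium held 9 called genes where 0.33 would fall by chance (adjusted p = 3.47e-08), among them Ifnb1, Gbp4, H2-K1 and Irf8, a transcription factor of macrophages and dendritic cells, which fell from 133 ± 6.85 to 81.6 ± 13.2 FPKM (SD, n = 2 each). Cellular response to interferon-gamma held 7 where 0.27 would (adjusted p = 5.04e-06), among them Il12b, Ccl7 and Gbp8 (log2 change −0.73). The elastase Mmp12, a macrophage protease, also fell (−0.86). Some terms share members, and Gm14023, which is counted in a few of them beside Il1a, overlaps that gene. Fisher's test takes genes as independent units, so its p does not measure the spread between libraries. Of the 61 genes, 47 were also raised by LPS, where independent lists would share 10.5. Immune terms may therefore restate that LPS-raised genes were lower.

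Among the genes higher in Glul_LPS, 0 terms passed with Fisher's exact test, and the smallest p was that of response to oxidative stress (5 called genes where 0.56 would fall by chance, p = 0.000231, adjusted p = 0.302). They included Nqo1, Hmox1 and catalase. Several genes that LPS lowered were higher in Glul_LPS while staying below control. Genes called lower with LPS and higher in Glul_LPS numbered 42, where independent lists would share 40.8, so they were not over-represented as deposited. That expectation depends on the scaling, since LPS lowered 7459 genes as deposited and 3530 after centring. Tgfbi stood at 157, 60.9 and 108 FPKM in control, LPS and Glul_LPS, Stab1, a scavenger receptor, at 74.8, 22.8 and 34.0 FPKM, and Cebpa at 62.5, 1.79 and 3.61 FPKM.

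After LPS most genes were lower and fewer were detected (17269 to 17525 above 0, against 19218 and 19095 in control). Depth was argued against, since after thinning to 12000000 fragments the lowest control library still had 1361 more detected genes than the highest LPS-treated library, where replicates differed by up to 181. Reads taken by the 821 raised genes, 4.62% and 4.37% of fragments in control and 27.3% and 26% in LPS, were argued against for the detected genes, since thinning all other fragments to 9000000 left a gap of 1027, but stay open for the lower values, since rescaling to the other fragments moved the median of all tested genes from −0.50 to −0.198, between the bounds for and against. Low-level background reads in control were narrowly argued against as the whole cause, as genes with a mean of at least 10 FPKM were at −0.277 (−0.293 to −0.252 over the 4 library pairs). Both together may account for the pattern, with these genes at 0.089 and lower genes at −0.38 after that rescaling, but a fall of weakly expressed genes through LPS would look the same and stays open. The level split used the mean over all 6 libraries, most of them LPS-treated, so genes that LPS raised reached 10 FPKM more easily. Part of the difference between 0.089 and −0.38 may follow from that selection.

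Glul was only slightly higher in the libraries labelled as overexpressing it. Too few fragments were argued against by the upper bound of the ratio, 1.28. Reads assigned to the pseudogene Glns-ps1 were argued against by its level of at most 0.114 FPKM in Glul_LPS. Reads that match both genes may have been counted for neither, which that level cannot show. An exchange of 1 library between LPS and Glul_LPS could not be judged by Glul, which did not pass between them. Its highest LPS value, 33.4 FPKM, lay below its lowest Glul_LPS value, 37.2 FPKM. In a fit of only these 2 groups, limma called 59 genes as labelled and 0 for the other splits of the 4 libraries. That goes against an exchange, though 3 splits are few. Candidate explanations that were not tested are a vector-borne copy that differs from the annotated gene or lacks most of its exon length, weak expression from the vector, and a sample from outside these groups under a wrong label. A small rise through the vector also stays open.

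Genes strongly raised by LPS were mostly lower in Glul_LPS. A share of cells that did not respond to LPS was argued against as the whole cause. The 14.3% of cells it needs would raise the 45 genes that LPS lowered by at least 3 log2 units by a median of 1.16. A median of 0.181 was observed (34 of 45 above 0). Its SE of 0.04 came from a bootstrap over genes and does not measure the spread between libraries. A smaller share stays open, as the observed median has the same sign. For all raised genes, 1 common factor was argued against by an SD over genes of 0.315, which is 3.61 times their median SE of 0.09. Chance values of single LPS or Glul_LPS libraries stay open, since with the LPS libraries divided between the comparisons the mean covariance of −0.0596 was −3.83 times its spread of 0.0155 from the replicate differences (0.0304 for LPS and −0.0066 for Glul_LPS), where 2 degrees of freedom ask for 4.3 to argue against them. Among the 3 splits of these 4 libraries limma called 59 genes for the real groups and at most 0 for the others (1669 against at most 300 at an unadjusted p below 0.05), and 3 splits are too few for a share below 0.05. The Glul vector may be a cause but was not tested, since a difference in culture or handling between the LPS and Glul_LPS cells is confounded with the groups and no Glul group without LPS was analysed here.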
